A study of Cricetulus griseus with 8 samples.

How the data were processed

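Ribosome profiling and mRNA sequencing were performed on Chinese hamster ovary (CHO) cells, an established cell line, that expressed an RNG140-GFP fusion protein, and on control CHO cells. Ribosome profiling digests RNA that is not covered by ribosomes and sequences the protected fragments, called footprints, so that footprints on an mRNA count the ribosomes on it. The 8 libraries formed 4 groups of 2: control footprints, RNG140-GFP footprints, control RNA and RNG140-GFP RNA. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, footprints came from RNase I digestion and ribosome pelleting followed by linker ligation and rRNA depletion, whereas the RNA libraries were made with a stranded mRNA kit.

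The authors deposited 1 table per library with a transcript identifier, a length and a whole-number count of reads per transcript, without a header and without normalization. CASAVA 1.8, Bowtie2 2.1.0 and TopHat2 2.0.9 are named per the submitters' processing notes, which were used here without their roles. The genome build, the annotation and the counting step are not given in the sources used here. Each table listed the same 34490 transcripts, of which 26985 had a length. The 7505 transcripts without a length had a count of 0 in every library, and so had 18 identifiers without the prefix of the others. The length had no stated unit. Its median was 380, its lowest value was -9, and 32.7% of the lengths were divisible by 3. It was read here as a coding length, probably in codons and less a trimmed part, which the sources used here do not state. It is called the listed coding length, and it serves to rank transcripts, except in the curves for coding region ends, which use its values.

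The files pair no identifier with a gene name, and 0 identifiers were found in the reference gene table. Genes are therefore not named, no genomic positions are given, and the level of the RNG140 (caprin2) mRNA was not analysed here. Gene lists for pathways and cell types, a check of mRNAs of the mitochondrial genome and a scaling on them had been fixed before the data were examined and could not be run. Lengths were to come from a reference and were taken from the deposited tables instead, so that coding length was tested and whole-transcript length was not. The rule for named transcripts took the largest changes among those with an adjusted p under 0.05, a mean of at least 10 CPM (counts scaled to library size) over the 8 libraries, and both RNG140-GFP values beyond both control values. For translation efficiency these values were ratios of footprint CPM to RNA CPM formed by replicate number. The rule was restricted to genes with symbols, always named Caprin2 and Caprin1, and took 12 genes per direction in RNA, footprints and translation efficiency. With no symbols, it was applied to translation efficiency alone and to 2 transcripts in each direction. Other large changes in RNA and footprints are given by listed length, were taken from the largest 3 per direction under the same rule, and were chosen for the text after their values were seen. A fold against a group with fewer than 3 counts was computed against a floor of 3 counts over the group.

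Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test with trimmed mean of M-values, TMM, scaling). All 8 libraries were fitted as 4 group means that shared 1 estimate of the spread, with 4 residual degrees of freedom. Contrasts gave the change in RNA, the change in footprints and, as their difference, the change in translation efficiency (footprints relative to RNA). Transcripts had to pass edgeR's expression filter (minimum count 10) in the RNA libraries and in the footprint libraries. This left 15577 transcripts, which held between 99.38% and 99.78% of the counts of each library. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors are Wald errors from the quasi-likelihood fit, never below the error of counting alone. CPM values use TMM-scaled library sizes. In data simulated for these 15577 transcripts from the real means, library sizes and common dispersion, with 67 or fewer transcripts changed by each size in translation efficiency, the test recovered 56.7% of 1.5-fold, 85.1% of 2-fold and 100% of 4-fold changes in translation efficiency. The corresponding values were 92.5%, 97% and 100% for RNA and 67.9%, 91% and 100% for footprints. Of the transcripts simulated as unchanged, 0.0455% were called in translation efficiency. Few transcripts were changed in the simulation, which makes its adjusted threshold stricter than that of the real data.

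Reads that fit several transcripts appear to have been counted on each of them: 3695 transcripts held the same counts as another transcript in all 8 libraries. Column totals therefore overstate the number of reads, and neighbouring transcripts are not independent tests. Transcripts were also joined into 10627 groups that appear to share reads, where neighbouring rows had identifier numbers at most 3 apart or where counts lay within 0.03 on a natural log scale in all libraries. Confidence intervals of class medians come from 1000 bootstrap draws of these groups. Correlations across transcripts are Spearman's rho with two-sided permutation tests of 100000 resamples, and 6 relations were adjusted together. Levels per library are log2 CPM with a prior count of 2, or with 0.1 CPM added where the change was set against control translation efficiency. Transcripts are not independent replicates.

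Replicates of each group correlated between r = 0.986 and r = 0.997 on log2 CPM, and the biological coefficient of variation of the fit was 0.046. Differences between replicates exceeded counting noise in every group, with chi-square per degree of freedom between 2.5 and 5.11, so that no library was counted as a duplicate. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicates were treated as unpaired. No spike-in is named in the labels, so each change is relative to the bulk of transcripts of the same library.

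Alternatives comprised other size factors, scaling within each assay, DESeq2 1.42.0, other filters, a threshold of 0.01, a replicate block, fits of 1 assay alone and leaving out each library. Keeping 1 transcript per group that appears to share reads and thinning the footprint libraries to 1 total were added after seeing the data.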

Results

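Gene expression and translation were measured in CHO cells that expressed RNG140-GFP and in control CHO cells, by RNA sequencing and ribosome profiling, with 2 libraries per group. RNG140, also called caprin2, is an RNA-binding protein of cytoplasmic RNA granules. The study asked how its overexpression changes translation efficiency. Control footprint libraries held 9039123 and 4908885 counts and RNG140-GFP footprint libraries 12172867 and 16928311. Control RNA libraries held 35875108 and 31227762 counts and RNG140-GFP RNA libraries 27591895 and 22849263. The most abundant transcript took between 0.738% and 1.1% of the counts of a library. On the first principal component, with 75.5% of the variance, footprint and RNA libraries separated. On the second, with 19%, control and RNG140-GFP cells separated in both assays, with scores from -40.2 to -37.5 for the 4 control libraries and from 32.6 to 44.2 for the 4 RNG140-GFP libraries.

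The first comparison asked which mRNAs differed in level between RNG140-GFP and control cells. RNA levels differed for 9554 of 15577 transcripts (61.3%), of which 4827 rose and 4727 fell (edgeR quasi-likelihood test, adjusted p under the threshold of 0.05). Most differences were small: the median size among called transcripts was 0.45 on the log2 scale, with a median standard error of 0.086 over all tested transcripts. Over 2-fold, 410 transcripts rose and 445 fell. Against a minimum change of 1.5-fold, 1482 transcripts (9.51%) passed.

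A small set of transcripts was nearly absent from the RNA of one of the cell populations. Of the tested transcripts, 12 rose by more than 64-fold in RNA, in 5 groups that appear to share reads. A further 18, in 13 such groups, fell by as much. The lower level rested on 3 counts or fewer over the group for 7 of the 12 and for all 18, and was then set to 3 counts. Footprints were called in the same direction for all 12 that rose and all 18 that fell. Translation efficiency was called as falling for 8 of the 12 and for 0 of the 18, and as rising for 0 in both sets. The largest rise was that of ENSCGRT00000021939 and ENSCGRT00000021940, which have a listed coding length of 104 and hold the same counts, so they are 1 measurement. Their RNA went from 0.173 ± 0.079 CPM in controls to 254 ± 0.898 CPM in RNG140-GFP cells (SD, n = 2), with 9 and 4 counts in the control libraries. The log2 fold change was 10.44 ± 0.4 (SE). Another group, of 3 transcripts with listed lengths of 121, 909 and 763, rose by between 7.76 and 8.22 on the log2 scale. Its longest member held 2.34 and 1.99 CPM in control RNA and 512 and 528 CPM in RNG140-GFP RNA. Footprints of that member were present in controls, at 13.4 and 32.7 CPM, and reached 1350 and 1340 CPM in RNG140-GFP cells. Translation efficiency of the 3 transcripts changed by between -1.93 ± 0.49 and -1.79 ± 0.25 (SE) on the log2 scale. Their control ratios rest on low values. The member of listed length 121 had 20 and 10 RNA counts and 9 and 26 footprint counts in controls. In the other direction, a transcript of listed length 988 fell by 4.66 ± 0.16 (SE) on the log2 scale, from 40.1 and 44.8 CPM to 1.58 and 1.78 CPM. A transcript of listed length 1372 had 1457 and 1289 RNA counts in controls and 3 and 0 in RNG140-GFP cells, and its footprints went from 186 and 96 counts to 0 in both. Among all listed transcripts, 16 with at least 1 CPM in control RNA had a count of 0 in both RNG140-GFP RNA libraries. Set against a floor of 3 counts over the group, their median decrease was at least 92.7-fold. In 13 of these 16, footprints reached 1 CPM in controls. A single transcript showed the reverse, with 0 counts in control RNA, and was at least 87.6-fold higher in RNG140-GFP RNA. Footprints were nevertheless counted on it in controls, whereas 12 of the transcripts absent from RNG140-GFP RNA had no footprint count in RNG140-GFP cells.

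The next comparison asked how ribosome occupancy differed. Footprints changed for 8144 transcripts (52.3%), of which 4039 rose and 4105 fell, with 779 rising and 577 falling by more than 2-fold. Footprint changes followed RNA changes across transcripts (Pearson r = 0.81, slope 0.91). Both values use all tested transcripts, including 47 that changed by more than 6 on the log2 scale in RNA or footprints. Such extreme changes, some against counts of 0, can weigh heavily in both values, and no rank correlation was computed. Of the transcripts called in both assays, 5607 moved in the same direction and 399 in opposite directions. The transcript of listed length 988 with the lower RNA fell by 6.88 ± 0.33 (SE) in footprints.

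**Figure D1:**
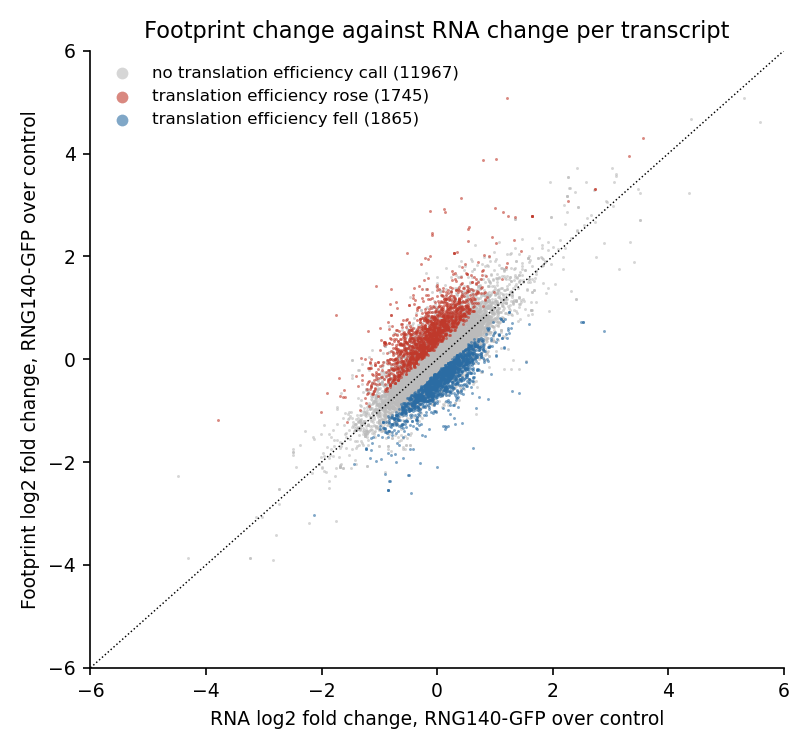
Footprint log2 fold change (vertical axis) against RNA log2 fold change (horizontal axis), RNG140-GFP over control, 1 point per transcript, with the line of equal change dotted. Red points are the 1745 transcripts whose translation efficiency rose, blue points the 1865 whose translation efficiency fell, and grey points the others; 47 transcripts lie outside the axes, which end at 6.

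Translation efficiency, the subject of the study, differed for 3610 transcripts (23.2%), of which 1745 rose and 1865 fell in RNG140-GFP cells (edgeR, interaction contrast, same threshold). The split depended on the processing: 1066 rose and 1624 fell in DESeq2, 1086 rose and 1354 fell without the first control RNA library, and 1919 rose and 1634 fell at a minimum count of 50. The changes were moderate: the 5th and 95th percentiles of all tested transcripts were -0.58 and 0.76 on the log2 scale, with a median standard error of 0.159. Over 2-fold, 223 transcripts rose and 82 fell. Against a minimum change of 1.5-fold, 133 passed. Translation efficiency changed without an RNA call for 1200 transcripts, in the direction of the RNA change for 868, and against it for 1542. The same RNA libraries enter both calls with opposite sign, so their noise by itself adds to the last count. A further 4513 transcripts changed in RNA and footprints alike with no call in translation efficiency.

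Under the rule for named transcripts, 1512 transcripts qualified as rising and 1772 as falling in translation efficiency. The largest rise was that of ENSCGRT00000015234, with a listed length of 33. This transcript lies in a group of 2 that appear to share reads, and it had 26 and 18 footprint counts in controls. Its RNA was 10.2 ± 0.161 CPM in controls and 11.1 ± 2.87 CPM in RNG140-GFP cells, while its footprints went from 3.91 ± 0.637 to 27.5 ± 1.52 CPM (SD, n = 2). Its translation efficiency rose by 2.73 ± 0.3 (SE; edgeR adjusted p = 3.08e-08). The next was ENSCGRT00000010712, with a listed length of 79, at 2.6 ± 0.68 (SE; edgeR adjusted p = 0.000544). Its RNA fell by 3.79 ± 0.66, from 51 and 41 counts to 3 and 2, and its footprints fell by 1.19 ± 0.15. The largest decrease was that of ENSCGRT00000021939 with its identical copy ENSCGRT00000021940, at -3.98 ± 0.44 (SE; edgeR adjusted p = 9.77e-09). It combined the RNA rise given above with a rise in footprints of 6.47 ± 0.19, from 5.23 ± 0.818 to 448 ± 28.7 CPM, and its control ratio rests on 9 and 4 RNA counts.

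Changes in translation efficiency were then compared between transcripts of different coding length. Translation efficiency rose more often than it fell among transcripts with short coding regions, and fell more often than it rose among those with long ones. In the shortest of 5 equal classes (listed lengths 15 to 201) the median change was 0.277 (95% interval 0.251 to 0.303), a 1.21-fold rise, and 873 transcripts rose while 129 fell. In the next class (202 to 344) the median was 0.08 (0.061 to 0.098), with 396 rising and 219 falling. The middle class (345 to 513) had a median of -0.007 (-0.024 to 0.009), which changed sign with the filter on low counts. The class from 514 to 810 had a median of -0.066 (-0.084 to -0.046), with 139 rising and 483 falling. The longest class (811 to 7641) had a median of -0.133 (-0.156 to -0.109), a ratio of 0.91, and 113 transcripts rose while 715 fell. Apart from the middle class, the medians kept their sign under every scaling and filter tried. Each scaling sets the bulk of transcripts near 0, so these signs are relative to that bulk. A shift of all classes together would not be seen.

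**Figure D2:**
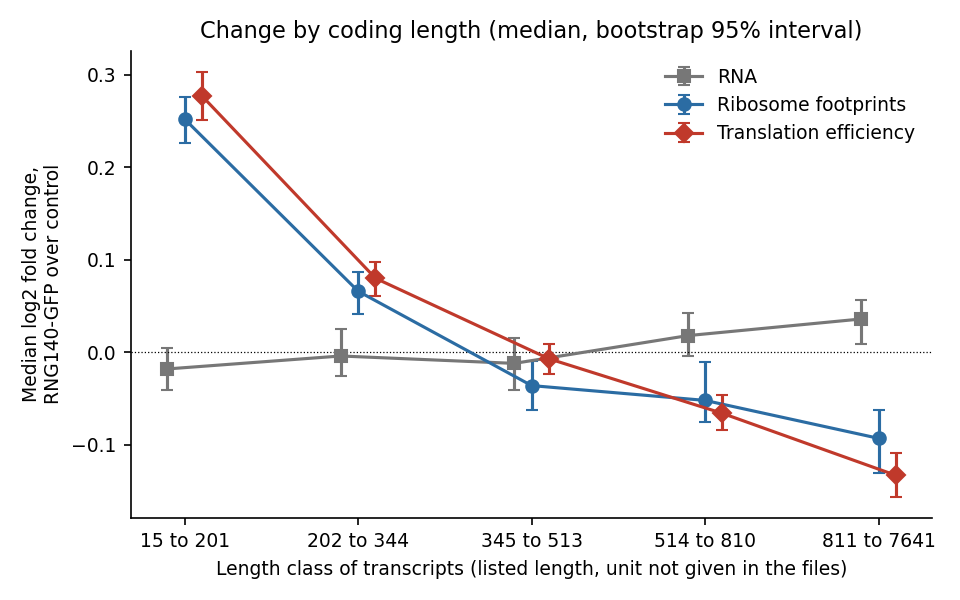
Median log2 fold change (vertical axis, RNG140-GFP over control) of RNA, footprints and translation efficiency in 5 classes of listed coding length (horizontal axis), with bootstrap 95% intervals. Translation efficiency and footprints fall from the shortest to the longest class, from 0.277 to -0.133 for translation efficiency, while RNA stays between -0.018 and 0.036.

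Across the 15577 transcripts the change in translation efficiency correlated negatively with length (rho = -0.339, permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 1.2e-05). With 1 transcript per group that appears to share reads, rho was -0.35 over 10627 transcripts, at the same p. Without a filter on low counts, rho was -0.208. The difference between the longest and the shortest class was -0.41 (95% interval -0.442 to -0.372) in translation efficiency and -0.345 (-0.388 to -0.306) in footprints. In RNA it was 0.054 (0.022 to 0.085), with rho = 0.032 (permutation p = 7e-05, adjusted p = 7e-05). Each RNG140-GFP footprint library set against each control footprint library gave a difference between -0.361 and -0.345, in 4 of 4 pairs. These pairs reuse the same 2 libraries per group and are not independent. The intervals and permutation tests resample transcripts and do not cover the spread between libraries. Replicates of the same group differed by no more than 0.014 between these classes.

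Transcripts with rising translation efficiency had a median listed length of 201, those with falling translation efficiency 666, and those without a call 429. The shortest class held 50% of the rising and 6.92% of the falling transcripts, and the longest class 6.48% and 38.3%. Among the 223 transcripts that rose by more than 2-fold, the median length was 113 and 72.6% lay in the shortest class. The 82 that fell by more than 2-fold had a median length of 399.5, and 25.6% of them lay in the shortest and 17.1% in the longest class, unlike the falling transcripts as a whole. Of the transcripts with a translation efficiency call but no RNA call, the rising ones had a median length of 198 and the falling ones 659. Within 3 equal classes of mean RNA level, rho was -0.213 in the low, -0.331 in the middle and -0.409 in the high class. Among the 6023 transcripts without an RNA call it was -0.316.

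The ratio of footprint CPM to RNA CPM, taken as the level of translation efficiency, varied with length in both cell populations. Footprint and RNA libraries were prepared differently, so a slope within 1 cell population cannot be told apart from a difference between the assays. In control cells the median log2 ratio of footprint CPM to RNA CPM was 0.23 and 0.22 in the shortest class (replicates 1 and 2) and -0.48 and -0.49 in the longest. In RNG140-GFP cells it was 0.52 and 0.51 in the shortest class and -0.58 and -0.6 in the longest. The span between classes was thus wider in RNG140-GFP cells, by more than the replicates differed.

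**Figure D3:**
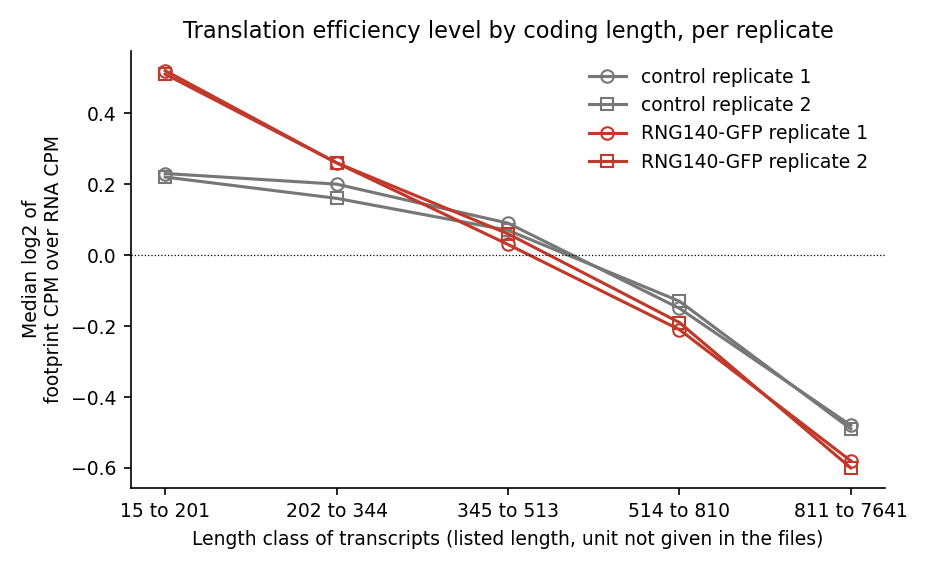
Median log2 ratio of footprint CPM to RNA CPM (vertical axis) in 5 classes of listed coding length (horizontal axis), 1 line per replicate number, control in grey and RNG140-GFP in red. RNG140-GFP replicates lie at 0.52 and 0.51 in the shortest class, above the controls at 0.23 and 0.22, and below the controls in the longest class.

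Finally, the change was compared with the translation efficiency that a transcript had in control cells. The control level was taken from one replicate and the change from the other, so that no control library entered both. Transcripts with a higher control translation efficiency moved down slightly relative to those with a lower one. The Spearman correlation was -0.13 with the level from replicate 1 and -0.16 with the level from replicate 2 (permutation p = 1e-05, the smallest possible, and adjusted p = 1.2e-05 for both). The split removes noise of single control libraries only. Deviations shared by both control replicates would also give a negative correlation, so no dependence on the control level is concluded. The shortest length class, with the highest median control levels (0.23 and 0.22), moved up, to 0.52 and 0.51.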

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

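Keeping 1 transcript per group and thinning were chosen after seeing the data, and so were, for the length correlation, the other size factors, DESeq2, the absent and either-assay filters and the blocks. The total counts of changed transcripts stayed within 1.5 times the reported ones under each alternative run, except that a threshold of 0.01 left 2042 calls in translation efficiency (983 rising, 1059 falling), which follows from the stricter threshold. By direction, the 1745 rising in translation efficiency became 1066 in DESeq2 (1624 falling) and 1086 without control RNA replicate 1 (1354 falling), and the 1865 falling became 1180 with 1 transcript per group that appears to share reads (1275 rising), where fewer were tested. Other size factors (RLE) gave 1554 rising and 2139 falling, and a minimum count of 50 gave 1919 and 1634; the cause of these shifts was not tested. No transcript called in both the reported fit and an alternative changed direction. Leaving out each library in turn gave 7974 to 8791 calls in RNA, 6296 to 7241 in footprints and 2440 to 3860 in translation efficiency; the lone library left in a group was assumed to vary like the others. DESeq2 called 7836, 7280 and 2690. A replicate block raised the counts to 9943, 8256 and 4017, and a block by culture gave 3961 in translation efficiency; same-numbered libraries deviated together by r = 0.01 in footprints and 0.13 in RNA, and no label says that the numbers pair libraries. With 1 transcript per group that appears to share reads, 6470, 5598 and 2455 were called among 10627. The correlation of the translation efficiency change with length lay between -0.375 (minimum count 50) and -0.208 (no filter on low counts), with -0.312 given the mean RNA level and -0.352 to -0.299 with 1 library left out. The correlations with control translation efficiency were -0.129 and -0.152 at a minimum count of 50. Alternatives for gene lists and a scaling on mRNAs of the mitochondrial genome were not run, for want of gene names. The footprint libraries held fewer counts than the RNA libraries, with 4908885 in the second control footprint library. Thinning the footprint libraries to that total left 6834 calls in footprints and 2813 in translation efficiency.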

Other observations

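The tests of coding region ends, RNA level by length, library preparation, thinned depth and 1 transcript per group, and the interval of the minimum-change test, were chosen after the results were seen. The curve with extra length in controls was added, and the rule changed to need both curves, after the curve without it had spoken against ends as the cause in the longest class; the share passing the minimum-change test lay on the side of the small-spread explanation before its interval was added. The 37 lowest-numbered identifiers form 1 consecutive block in which 13 transcripts have a listed length. These 13, unnamed in the files, took 1.32% and 1.39% of control RNA counts but 0.0225% and 0.0195% of control footprint counts. In RNG140-GFP cells they took 1.13% and 1.21% of RNA counts and 0.0152% and 0.0105% of footprint counts. Exact binomial 95% intervals of the footprint shares were 0.0216% to 0.0235% and 0.0183% to 0.0208% in controls, and 0.0145% to 0.0159% and 0.00999% to 0.011% in RNG140-GFP cells, covering counting error only. Of the 13, 10 fell and 1 rose in RNA, 11 fell in footprints with a median of -0.88, and 5 fell in translation efficiency with a median of -0.31 (edgeR, adjusted p under 0.05). The medians kept their sign under the other size factors and in DESeq2, where that of translation efficiency was -0.29. The block was singled out after its values were seen.

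The fall of the translation efficiency change with coding length is the pattern most worth following up. Argued against as the whole cause are footprint depth (rho = -0.317 after thinning all footprint libraries to 4908885 counts), reads shared between isoforms or near-identical copies (rho = -0.349 with 1 transcript per group), mRNA level (0.054 between the longest and shortest class) and length bias of the size seen between replicates (0.014 at most). A candidate explanation that stays open is that footprints at the ends of coding regions made up a larger part in RNG140-GFP cells: a curve with a fixed extra length, fitted to the shorter 6 of 10 length classes, left the mean of the longest 2 too low (-0.039, 95% interval -0.067 to -0.011), through class 10 (-0.058, -0.091 to -0.017) more than class 9 (-0.02, -0.057 to 0.014), but not once controls were allowed extra length too (-0.031, -0.061 to 0.022), and the mean of classes 7 and 8 lay within the interval of both curves (-0.018, -0.04 to 0.01, and -0.013, -0.035 to 0.024). From the shortest to the longest of the 10 classes, the curve without extra length in controls fell by 0.487, where the observed medians fell by 0.544. Most of the curve's fall lay within the 6 classes it was fitted to, from 0.382 in class 1 to -0.016 in class 6. The match in size is thus largely set by the fit, which needed an extra length of 44.2, and gives no support of its own. Whether reads at the ends were counted is not stated in the sources used here. The listed length was read as less a trimmed part. A constant trimmed part would act in the curves like the extra length in controls, fitted at 8, and cannot be told apart from it. If reads in that part were also left out of the counts, they could not add to the fall. A difference in footprint library preparation between the groups cannot be told apart from an effect of RNG140-GFP (rho = -0.216 for footprints alone), since no batch is given that holds both. An effect of RNG140-GFP and other differences between the cell populations both stay open and were not tested.

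Of the tested transcripts, 61.3% differed in RNA, and a candidate explanation is that a small spread between replicates lets small differences pass. Against a minimum change of 1.5-fold 1482 passed, 9.51% of those tested, and the bootstrap interval of that share (8.89% to 10.2%) spans the 10% set in advance, so this test does not settle it. The transcripts nearly absent from the RNA of one cell population are a separate feature, and whether they mark a difference between clones was not tested, as the labels do not say how the cells were derived.

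Changes in translation efficiency ran weakly against changes in RNA (rho = -0.151). Because RNA libraries enter both, the RNA replicates were split, which left rho at -0.083 and -0.096. Noise of single RNA libraries therefore does not account for all of it. Deviations shared by both RNA replicates of a group would also give a negative correlation, so no dependence on the RNA change is concluded. With the RNA change from replicate 1 and 2, median changes in translation efficiency were 0.08 and 0.1 where RNA fell by more than 2-fold, 0.07 and 0.11 in the class of smaller falls, 0.01 in both where RNA changed least, -0.02 and -0.03 in the class of smaller rises, and 0.02 and 0.05 where RNA rose by more than 2-fold. Relative to 0, the medians thus ran against RNA in both classes of falls and in that of smaller rises, but not in the last, which holds 406 and 441 transcripts. No intervals were computed for them. The zero point depends on the scaling: the median over all tested transcripts was 0.012 here and -0.018 with RLE size factors. Medians as near 0 as those in the classes of rises therefore do not settle a direction.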
